A study of Homo sapiens with 6 samples.

How the data were processed

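Polyadenylated RNA of ARPE-19 cells was sequenced after 24 h with 40 µM tt-DDE or DMSO, 3 libraries per group. Per the labels' protocols, total RNA was extracted with a column kit, mRNA was enriched on oligo(dT) beads, fragmented to about 300 bp, copied with random primers, amplified by PCR and size-selected to about 450 bp with adapters. Groups and replicate numbers were taken from the sample titles, and each data column from the library name in the labels.

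Per the file headers, the deposited table gives a read count and an FPKM for each gene and library, with coordinates, strand, length and a pathway annotation. The build was GRCh38.p13 per the submitters' processing notes. The aligner, the counting program, the annotation release and whether strand was used in counting are not given in the sources used here. The deposited counts are whole numbers with no normalization, per the file headers and the values. The FPKM that the authors deposited equalled the count divided by gene length and by the column total for all 91254 values above 0, within a relative tolerance of 1e-06, so the authors applied no composition factor to it. The table holds 22312 rows, of which 22119 matched a protein-coding gene by gene ID in the RefSeq table used for names. Of these rows 2805 are further copies of a symbol, most on alternate scaffolds, and 5099 rows had no count in any library. Counts of some such symbols are divided between rows, while others have them all in the first row or, like AKAP17A and ARHGAP11A, none there. The row on the primary chromosome was reported, with the sum for some genes that the text names. Mitochondrially encoded genes were not analysed here.

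Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, groups as the only term), two-sided, with Benjamini-Hochberg adjustment over the 12668 rows that passed the filter, of which 260 are further copies. The threshold was an adjusted p of 0.05. Values in CPM are scaled with the TMM factors, and SD is over 3 libraries. The counting floor and the CPM values under other observations are instead scaled to the column total alone. For some genes with few counts in a group, the ratio of summed counts is given with an exact 95% interval, or against a floor of 3 counts over the group where there were none. For others with few counts, such as DNAH17 and FBXO43, only the fitted log2 fold change is given, which is uncertain. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The common dispersion was 0.00139, a biological coefficient of variation of 3.73%, and the median standard error of a log2 fold change was 0.0744. Set tests used camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) for 30 lists with at least 5 genes tested. The same tests were repeated with an estimated correlation, and with fry, which asks whether a list's genes move on balance in a direction without comparing them with other genes. With an estimated correlation camera takes its degrees of freedom from the 6 libraries, and with a preset one from the genes tested. The estimated version can therefore give larger p-values without a larger correlation.

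The design, the gene lists, the rule for named genes and most alternatives below were fixed before the data were examined. Genes were named by 3 rules: the 10 largest rises and 10 largest falls among genes past the threshold, further copies of a symbol set aside, with all libraries of the groups apart and a mean of at least 5 CPM; up to 4 members of each list with the smallest p, plus the first of the rarer direction; and 26 genes fixed by name. A few further list members are named in the closing section, chosen after their values were seen. Lists covered NRF2 targets, aldehyde and glutathione detoxification, heat shock, endoplasmic reticulum chaperones, ATF4 and CHOP targets, p53 targets, G1/S, G2/M, NF-kB cytokines, interferon response, immediate early genes, cholesterol, fatty acid synthesis, fatty acid oxidation, glycolysis, respiratory chain, ribosomal proteins, lysosome and autophagy, proteasome, ferroptosis, metallothioneins, extracellular matrix, retinal pigment epithelium, junctions, complement, senescence, apoptosis, histones, and markers of leukocytes, endothelium, photoreceptors and neurons, and keratinocytes.

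Total counts were 14156421, 15900093 and 16061373 in DMSO libraries 1 to 3 and 17130543, 16445790 and 15548067 in tt-DDE libraries 1 to 3. Libraries of a group differed from each other by more than sampling noise (chi-square per degree of freedom 1.74 to 3.63 over genes with at least 20 counts in a pair), so none was counted as a repeat of another, and between groups the value was 312 to 357. In simulated counts for the same 12668 rows with a dispersion of 0.002, the test recovered 68% of 50 genes changed 1.25-fold, 82% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and called 8 unchanged genes. A shifted list was called and 0 of 20 unshifted lists were called by camera. The simulated genes were drawn independently and most were left unchanged, while 82.91% of genes were called in the data. The simulation therefore does not test camera where list members are correlated, nor the scaling where most genes change.

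Alternatives were another size factor, library size alone, DESeq2 1.42.0, limma voom, other filters on low counts, a test against a 1.5-fold change, a replicate block, each library left out, and limma on log2 FPKM with pseudocounts of 1 and 0.1. After the data were seen, 2 more were added: rows of a symbol summed, and the 50 rows of most counts left out. Figures were drawn with matplotlib 3.10.9.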

Results

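ARPE-19, an established human retinal pigment epithelial cell line, was exposed for 24 h to 40 µM tt-DDE (trans,trans-2,4-decadienal, an unsaturated aldehyde formed when linoleic acid is oxidised) or to its DMSO vehicle, and polyadenylated RNA was sequenced. The 2 groups held 3 libraries each. The deposited counts summed to 14156421 to 16061373 in the DMSO libraries and to 15548067 to 17130543 in the tt-DDE libraries. A row of the table needed 3 counts to stand above the counting floor, which was 0.175 to 0.212 CPM (counts scaled to the size of the library) in these libraries. The comparison asks which transcripts differed in these cells after the aldehyde.

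After tt-DDE, genes for heat shock proteins, for chaperones of the endoplasmic reticulum and for the ATF4 and CHOP branch of the stress response rose, with list medians of 1.47 to 2.50 on the log2 scale, and genes for mitosis and for DNA replication fell, with medians of -3.91 and -2.42. HSPA5, the main chaperone of the endoplasmic reticulum lumen, rose from 872 ± 20.4 to 20158 ± 301 CPM (SD, n = 3 in each group), a log2 fold change of 4.53 (SE 0.0344). TOP2A, a topoisomerase of dividing cells, fell from 637 ± 7.08 to 9.82 ± 1.65 CPM (SD, n = 3), a log2 fold change of -6.01 (SE 0.0593). Of 12668 genes tested, 5244 were higher and 5259 lower, and 2165 did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05). The change was at least 2-fold in 2039 genes that rose and 2132 that fell, at least 4-fold in 605 and 578, and at least 16-fold in 136 and 53. These directions are relative to the TMM scaling, under which the median log2 fold change of all genes was -9e-04. With library size alone 45.55% of calls were higher, against 49.93% with TMM. In 83.6% of the genes tested all libraries of 1 group lay above all of the other, where chance gives 10%. The first principal component held 93.76% of the variance and separated the groups. On the log2(FPKM + 1) scale limma called 888 genes at least 2-fold higher after tt-DDE and 1552 genes at least 2-fold lower after tt-DDE, so that 36.4% of such calls were higher, against 48.89% on counts.

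**Figure D1:**
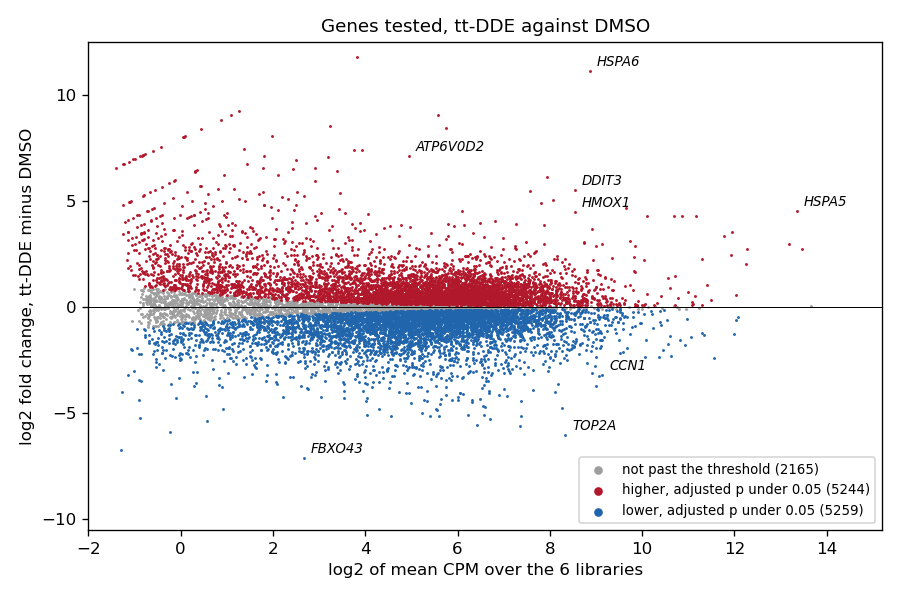
Log2 fold change (tt-DDE minus DMSO) against the log2 of the mean CPM over the 6 libraries, with 1 point per gene tested, coloured by direction where the adjusted p was under 0.05. The 5244 genes that were higher and the 5259 that were lower spread over the range of expression, and points above HSPA6 or between it and ATP6V0D2 include copies of HSPA1A and HSPA1B, with HSPA6 at 11.16 and FBXO43 at -7.12.

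Among genes of at least 5 CPM on average, with further copies of a symbol set aside, the largest rise was that of HSPA6 (chromosome 1, 161524540 to 161526894), an inducible cytosolic HSP70, from 0.401 ± 0.0352 to 932 ± 110 CPM (SD, n = 3). The 19 counts it had in the DMSO libraries and the 44292 in the tt-DDE libraries give a ratio of 2325-fold, 95% counting interval 1489 to 3863. HSPA1A followed, with 2 counts in DMSO and 876 after tt-DDE (437-fold, 95% counting interval 121 to 3613). The log2 fold change of HSPA1A was 8.55 with all libraries, 11.20 without DMSO library 3 and 7.57 without tt-DDE library 3. This row held only 10.39% of the counts of its symbol, and the sum of the 5 rows gave 8.56. ATP6V0D2, a subunit of the vacuolar proton pump, rose from 0.414 to 61.0 CPM, ZFAND2A, an arsenite-inducible proteasome-associated protein, from 6.90 to 487 CPM, and DDIT3, the transcription factor CHOP, from 15.6 to 735 CPM. The log2 fold changes of DNAH17, GCNT3 and DCDC2C were 7.42, 6.94 and 6.43, from 4 to 11 counts in DMSO. The log2 fold change of OLAH was 7.08, or 8.82 without DMSO library 2, and the log2 fold change of RASGEF1B was 5.95, or 6.76 without DMSO library 2 and 5.34 without DMSO library 3. The largest fall was that of FBXO43, an inhibitor of the anaphase-promoting complex, with 606 counts in DMSO and 4 after tt-DDE (log2 fold change -7.12, SE 0.303). CYP24A1, the vitamin D 24-hydroxylase, fell from 320 to 6.73 CPM. The other 8 of the 10 largest falls, TOP2A, CDK1, KIF20A, KNL1, ASPM, NEK2, NDC80 and KIF2C, are genes of chromosome segregation or mitotic entry, with log2 fold changes from -5.07 to -6.01. Among these 20 genes the weakest adjusted p was 3.54e-15 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, HSPA1A).

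**Figure D2:**
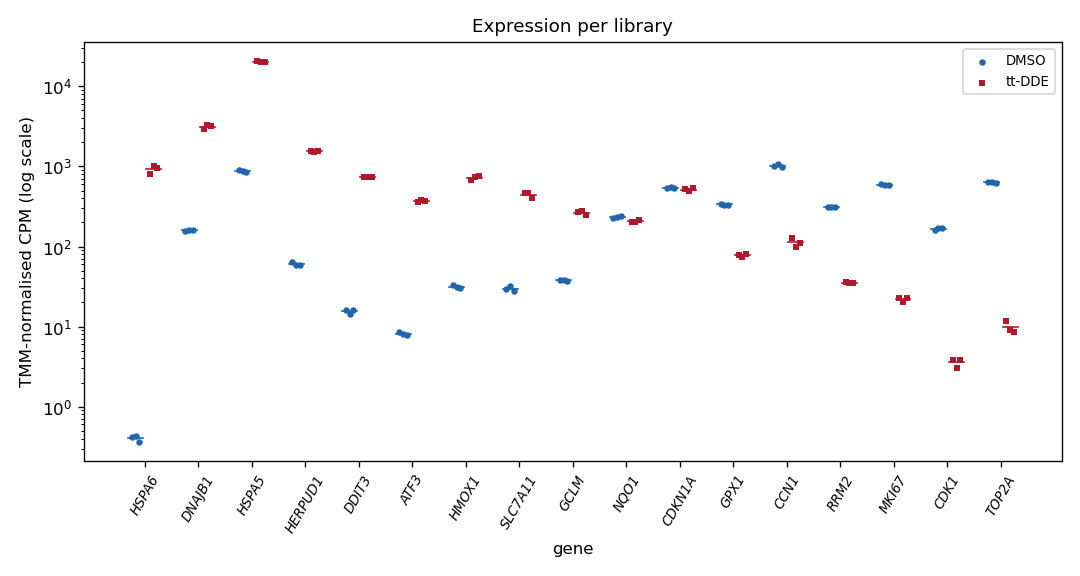
Expression of 17 named genes in each library as TMM-normalised CPM on a log axis, with circles for the 3 DMSO libraries, squares for the 3 tt-DDE libraries and bars for group means. HSPA5 moved from 872 to 20158 CPM and TOP2A from 637 to 9.82 CPM, and the points of each group lie close together next to that distance, while CDKN1A libraries overlap.

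Members of the cytosolic heat shock list rose without exception: 26 of 26 tested, with a median log2 fold change of 2.33, and 22 of them by at least 2-fold. HSPH1, a nucleotide exchange factor of HSP70, rose from 220 to 4355 CPM, DNAJB1, an HSP40 co-chaperone, from 159 to 3141 CPM, BAG3 from 106 to 2114 CPM, and the constitutive HSPA8 from 2883 to 19583 CPM. The list ranked above other genes with camera adjusted p = 9.09e-10, and adjusted p = 0.212 with an estimated correlation. Endoplasmic reticulum chaperone and degradation genes did likewise, 23 of 23 tested, at a median of 2.50 (camera adjusted p = 9.09e-10, and adjusted p = 0.148 with an estimated correlation). HERPUD1 had a log2 fold change of 4.68, DNAJB9 of 4.93 and HSP90B1 of 2.78. Adjusted over the list alone, the counts were 26 and 23 too.

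Targets of ATF4 and CHOP, which control amino acid supply and stress-induced transcription, rose in 29 of 30 cases tested, with a median of 1.47 (camera adjusted p = 1.18e-08, and adjusted p = 0.0478 with an estimated correlation). ATF3 rose from 8.17 to 370 CPM, TRIB3 from 15.7 to 521 CPM and SLC3A2, the heavy chain of amino acid exchangers, from 178 to 3553 CPM. STC2 fell (-1.06). GDF15, a stress-induced cytokine, was near the floor in DMSO, with 14 counts against 94 after tt-DDE. The log2 fold change of GDF15 was 2.71, or 3.54 without DMSO library 3. The count adjusted over the list alone was 29 higher and 1 lower.

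Most NRF2 antioxidant targets rose: 22 of 29 tested were higher, 4 lower and 3 not past, the same adjusted over the list alone. The median log2 fold change was 1.23, with 17 at least 2-fold higher and 0 at least 2-fold lower. HMOX1, heme oxygenase, rose from 31.6 ± 1.13 to 720 ± 43.5 CPM (SD, n = 3), and SLC7A11, the cystine transporter, from 29.6 to 443 CPM. GCLM, a subunit of the enzyme that limits glutathione synthesis, had a log2 fold change of 2.81, OSGIN1 of 4.00, and the ferritin chains FTL and FTH1 of 2.49 and 1.48. NQO1 and TKT fell slightly (-0.18 and -0.27). The list's camera adjusted p = 0.000115, and adjusted p = 0.143 with an estimated correlation. In the other direction, 23 of 29 tested genes for aldehyde and glutathione detoxification fell, 3 rose and 3 did not pass, again the same adjusted over the list alone (camera adjusted p = 0.00151, and adjusted p = 0.425 with an estimated correlation). Glutathione peroxidases GPX1 and GPX4 fell (-2.11 and -1.07), as did the aldehyde dehydrogenases ALDH7A1 and ALDH1B1 (-2.33 and -2.08), while ALDH2, the mitochondrial aldehyde dehydrogenase, rose (2.44).

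Lysosome and autophagy genes rose in 31 of 39 cases tested and fell in 4, and the list kept its call in both tests (camera adjusted p = 1.81e-05, and adjusted p = 0.0478 with an estimated correlation). MAP1LC3B and GABARAPL1, which coat autophagosomes, had log2 fold changes of 2.90 and 3.92, and the cathepsin CTSZ fell (-0.68). SQSTM1, an autophagy receptor, rose by 2.52 on a row with 7.53% of its symbol's counts, and by 3.22 over its summed rows. Proteasome subunits rose in 27 of 31 cases and 4 did not pass, with a median of 0.63 (camera adjusted p = 3.07e-06, and adjusted p = 0.205 with an estimated correlation); PSMD12 and PSMD3 had log2 fold changes of 1.23 and 1.13. Adjusted over the list alone, 31 lysosomal and 27 proteasomal genes were higher. Replication-dependent histone rows, whose transcripts normally lack a poly(A) tail and which served as a sign of RNA quality and poly(A) selection, rose in 10 of 13 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.179 with an estimated correlation). H2BC21 rose from 2.82 to 14.1 CPM and H2BC4 had a log2 fold change of 2.71. The log2 fold change of H2BC12 was -0.18, a call lost without DMSO library 3 (-0.12) and without tt-DDE library 2 (-0.14).

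Cell cycle genes fell together. All 37 tested genes of G2/M and mitosis were lower, 36 of them by at least 2-fold, with a median log2 fold change of -3.91 (camera adjusted p = 1.98e-14, and adjusted p = 0.0478 with an estimated correlation). MKI67, a marker of proliferating cells, fell from 590 ± 15.1 to 22.0 ± 1.39 CPM (SD, n = 3), CCNB1, the mitotic cyclin, from 374 to 24.9 CPM, and CDK1, its kinase, from 167 to 3.57 CPM. Of 36 genes of G1/S and DNA replication, 34 fell and 2 rose, with a median of -2.42 (camera adjusted p = 4.24e-10, and adjusted p = 0.0478 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, was at -3.15, MCM4 at -2.94 and PCNA at -3.04, while CCNE1, cyclin E1, rose by 0.63. The counts adjusted over the list alone were 37 and 34 lower. The replication-dependent histone rows moved opposite to both lists. The 10 rows of most counts held 5.13% to 5.27% of counts in DMSO and 10.60% to 10.96% after tt-DDE, where the top row was HSPA5 or HSPA8.

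Extracellular matrix genes and targets of TGF-beta fell in 20 of 28 cases and rose in 6, also adjusted over the list alone (camera adjusted p = 0.00313, and adjusted p = 0.171 with an estimated correlation). CCN1, a matricellular protein, fell from 1017 to 113 CPM, THBS1 from 250 to 29.4 CPM, and LOXL2, a collagen crosslinking enzyme, from 258 to 34.2 CPM. COL1A1 and MMP1 rose (2.51 and 1.85). Of 46 nuclear-encoded respiratory chain subunits 37 fell, 2 rose and 7 did not pass, with a median of -0.52 and the same count adjusted over the list alone (camera adjusted p = 1.81e-05, and adjusted p = 0.332 with an estimated correlation). ATP5MC1, NDUFV1 and CYC1 were at -2.15, -1.18 and -1.05, and NDUFC2 at 0.76.

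**Figure D3:**
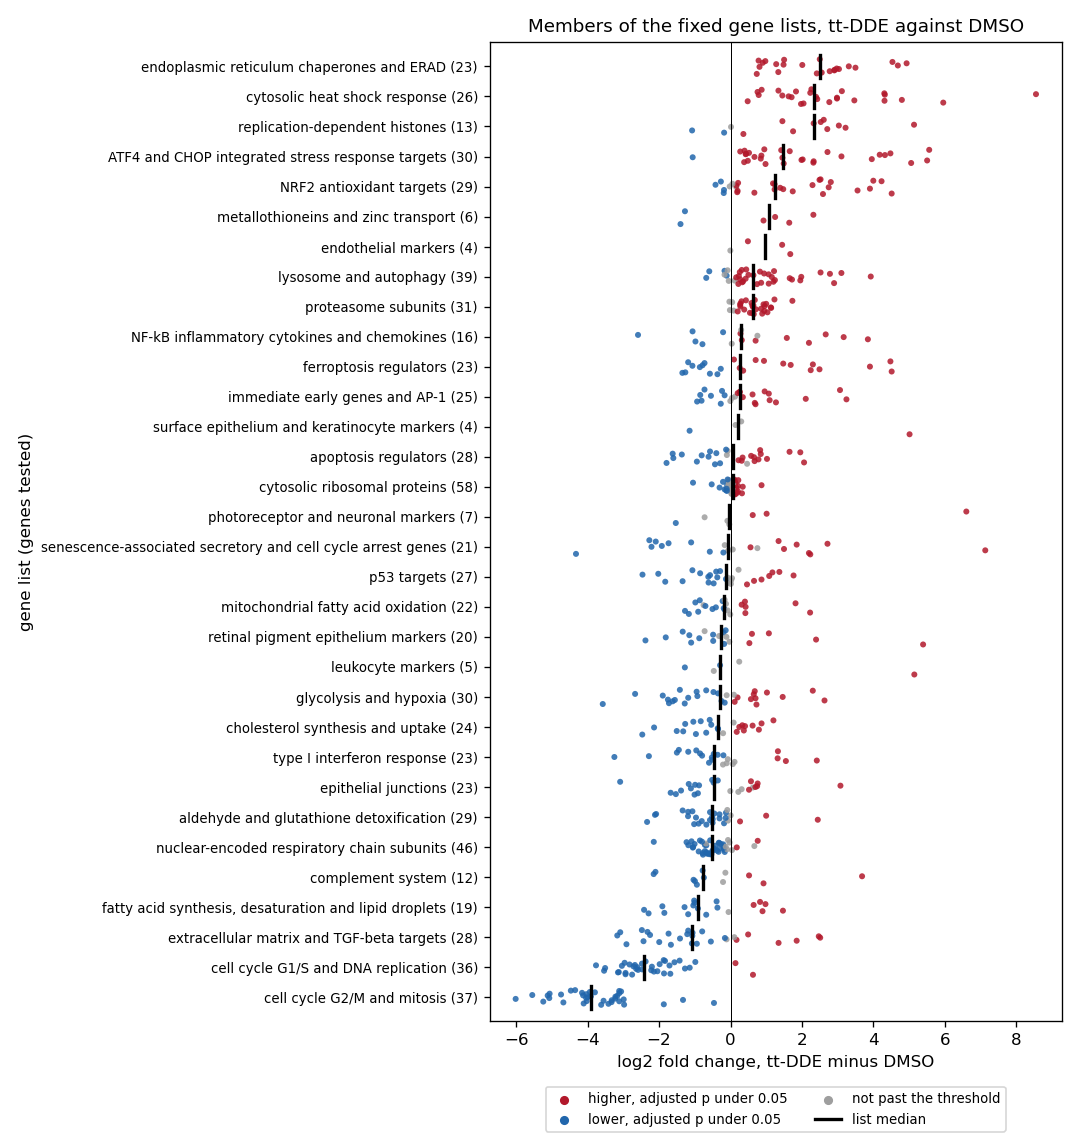
Log2 fold change (tt-DDE minus DMSO) of each tested member of 32 fixed gene lists, coloured by direction where the adjusted p was under 0.05, with a black bar at the list median. The medians run from -3.91 for G2/M genes to 2.50 for endoplasmic reticulum chaperones.

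Lists for lipid and sugar metabolism, ribosomal proteins, ferroptosis and metallothioneins moved both ways, and camera called none of these fixed lists. Of 19 genes for fatty acid synthesis and lipid droplets 13 fell and 5 rose (camera adjusted p = 0.135), among them the elongase ELOVL6 (-2.42) and PLIN2, a lipid droplet coat protein (1.47). Cholesterol synthesis had 13 lower and 9 higher of 24 (camera adjusted p = 0.334), with EBP at -2.14 and HMGCS1 at 1.20. Mitochondrial fatty acid oxidation had 11 lower and 6 higher of 22 (camera adjusted p = 0.324), with ACADM at -1.27 and PPARA at 1.82. Glycolysis and HIF1 targets had 17 lower and 11 higher of 30 (camera adjusted p = 0.334): the glycolytic enzymes ENO1, PFKP and PGAM1 fell (-1.75, -1.90 and -1.62), and NDRG1 and the growth factor VEGFA rose (2.63 and 2.30). The annotated pathway of glycolysis and gluconeogenesis, looked at after the results were seen, had 29 lower and 8 higher of 42. It was called lower (camera adjusted p = 0.0171 over 311 pathways, and adjusted p = 0.557 with an estimated correlation). Ribosomal proteins had 27 higher, 10 lower and 21 not past of 58 (camera adjusted p = 0.374), and their median of 0.06 was -0.02 when only library size was scaled. RPL28 was at 0.34 and RPS24 at -0.53. Ferroptosis regulators had 13 higher and 10 lower of 23 (camera adjusted p = 0.393), with the zinc and iron importer SLC39A14 at 2.24. Metallothionein and zinc transport genes had 4 higher and 2 lower of 6 (camera adjusted p = 0.412): MT1E and MT2A fell (-1.40 and -1.27), and the zinc exporter SLC30A1 rose (1.64). The counts of the fixed lists were the same adjusted over the list alone, except 26 higher ribosomal proteins.

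Inflammatory, p53 and survival lists also had members moving both ways, and camera called none of these. NF-kB genes (fry adjusted p = 5.81e-05) and immediate early genes (fry adjusted p = 0.00397) were higher on balance. Interferon (fry adjusted p = 0.000193) and p53 genes (fry adjusted p = 0.00392) were lower on balance. For BCL2 family and caspase genes the direction by fry was down (fry adjusted p = 0.000834). Their median of 0.07 and their direction by camera were up, so that call gives the list no clear direction. Senescence genes were not called (fry adjusted p = 0.173). Most lists of the other paragraphs were called by fry as well, such as ferroptosis (higher, fry adjusted p = 1.19e-06) and junctions (lower, fry adjusted p = 2.07e-05). A call by fry therefore does not set a list apart. Among 16 cytokine and NF-kB genes 8 rose and 5 fell (camera adjusted p = 0.334). IL11 rose from 3.01 to 43.6 CPM, CXCL3 from 2.60 to 23.5 CPM and CXCL8, interleukin 8, from 10.1 to 46.2 CPM, whereas LIF fell (-0.98). IL6 was at 0.419 to 0.716 CPM, which did not pass with all libraries and passed without DMSO library 2 (log2 fold change of IL6 1.27). Interferon response genes had 14 lower and 4 higher of 23, and 13 lower adjusted over the list alone (camera adjusted p = 0.139), with OAS3 at -3.25 and HERC5 at 1.55. Immediate early genes had 14 higher and 8 lower of 25 (camera adjusted p = 0.374), with MAFF at 2.11 and FOSL2 at -0.94. Targets of p53 had 14 lower and 7 higher of 27 (camera adjusted p = 0.374): PLK2 and DDB2 fell (-2.46 and -2.02), and the death receptor TNFRSF10B rose (1.76). CDKN1A, the p21 inhibitor, was at 541 ± 8.53 and 515 ± 25.2 CPM (SD, n = 3) and did not pass, although the log2 fold change of CDKN1A passed at -0.10 without tt-DDE library 3 and at -0.16 with library size alone. Senescence-associated genes had 9 lower and 8 higher of 21 (camera adjusted p = 0.981), with a median of -0.07, a mean of 0.17 and a test direction of down. LMNB1, lamin B1, fell from 95.3 to 4.76 CPM. BCL2 family and caspase genes had 13 higher and 12 lower of 28 (camera adjusted p = 0.981), with BCL2L1 at -1.62, BOK at -1.60 and a list median of 0.07 that was -0.02 with library size alone. Except for the interferon list, counts were the same adjusted over the list alone.

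Of 20 tested retinal pigment epithelium markers 11 fell and 5 rose (camera adjusted p = 0.290). The keratins KRT8 and KRT18 fell (-1.81 and -1.34), as did ezrin, EZR (-1.15). RPE65, the retinoid isomerase, had 0 counts in the 6 libraries and was not detectable at this depth. BEST1 rose by 5.39, but it overlaps FTH1 on the other strand, which was at 895 to 2488 CPM. Junction genes had 13 lower and 6 higher of 23 (camera adjusted p = 0.283), with CLDN11 at -3.09, DSP at -1.11 and CTNNA1 at 0.52. Complement genes had 7 lower and 3 higher of 12 (camera adjusted p = 0.315): CD59, which blocks the membrane attack complex, fell from 1192 to 269 CPM, and clusterin, CLU, rose from 70.1 to 901 CPM. Most markers of other cell types had too few counts to be tested. Leukocyte markers had 1 higher and 2 lower of 5 tested (camera adjusted p = 0.753), where the median of -0.29 and the mean of 0.67 differed in sign, the test direction was down and CD14 had 2 counts in DMSO against 84 (41.9-fold, 95% counting interval 11.2 to 352). Photoreceptor and neuronal markers had 3 higher and 1 lower of 7 (camera adjusted p = 0.412), a median of -0.03 and a mean of 0.84, or 0.41 with RBFOX3 at its bound, and a test direction of up. RBFOX3 had 0 counts in DMSO and 36 after tt-DDE, at least 11.97-fold higher against a floor of 3 counts over the group, and TUBB3 was at 1.01. Endothelial markers had 3 higher of 4 tested, among them ROBO4 (0.49), and keratinocyte markers 1 higher (ESRP1, 1 count against 44, 43.9-fold, 95% counting interval 7.48 to 1772) and 1 lower (KRT15) of 4, too few for a set test. The log2 fold change of ESRP1 was 5.01, or 6.87 without DMSO library 2. For every list of this paragraph the counts were the same adjusted over the list alone.

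Nothing in the labels says that the replicates were separate cultures, so these p-values measure only the spread between these libraries, which may be technical. Strand of the counting is not given in the sources used here, so values are uncertain where genes overlap, as for DDIT3, DNAJB1, KIF20A, DNAH17, TNFRSF10B, BEST1 and FTH1, KRT8 and KRT18, CLU, CD59, EZR, THBS1, NDUFC2, RPL28, CTNNA1, VEGFA, SQSTM1, H2BC12 and CD14, and where near-identical copies share reads, as for HSPA1A and HSPA6, ferritins, metallothioneins, histones and ribosomal proteins.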

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

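The summed rows of a symbol and the removal of the 50 rows of most counts were chosen after the data were seen; the other alternatives were set beforehand. Counts of calls stayed within 1.5 times their reported values under other size factors, library size alone, DESeq2, limma voom, other count filters and both added settings. They did not in these cases: against a 1.5-fold change edgeR called 2849 genes higher after tt-DDE and 2988 genes lower after tt-DDE, since the test asks for more, and limma on FPKM called 888 genes at least 2-fold higher after tt-DDE with a pseudocount of 1, 891 without a filter and 1203 with a pseudocount of 0.1. Of calls of at least 2-fold, 36.4% were higher with a pseudocount of 1 and 37.4% with 0.1, against 48.89% as reported and 42.8% with library size alone, which like the deposited FPKM has no composition factor; the cause was not tested. With an estimated correlation camera called 2 lists higher (ATF4 and CHOP targets, lysosome and autophagy) and 2 lower (both cell cycle lists). For the 2 higher lists the estimates, -0.0074 and -0.006, lay below the preset 0.01. Their camera adjusted p still went from 1.18e-08 and 1.81e-05 to 0.0478, which argues against a larger correlation as the reason for these lists. By fry, which tests each list alone, 12 were higher and 15 lower. With a preset correlation camera takes its degrees of freedom from the genes tested, and with an estimated one from the 6 libraries. The estimated version therefore gives larger p-values even where the correlation is no larger. How much of each difference between tests came from this was not tested. Leaving out each library in turn gave 5164 to 5219 genes higher, 5146 to 5231 lower, 2064 to 2159 at least 2-fold higher and 2115 to 2216 genes at least 2-fold lower after tt-DDE, with 7 lists higher and 5 lower each time. Same-numbered libraries hardly deviated together (r across genes 0.0225, 0.0088 and 0.0029, against -0.0169 to 0.0081 for other pairs). Counting noise could hide a small shared effect, so pairing is not excluded. With the replicate number as a block, 5211 genes were higher and 5234 lower, 2040 and 2137 at least 2-fold, and 7 and 5 lists were called. Of the genes named by rule none reversed, 16 calls were lost, 13 of them against a 1.5-fold change, and 9 were gained. RPL7A, named after its values were seen, did reverse: its call of -1.05 turned to 1.24 when rows of a symbol were summed, on means of 11.9 ± 1.41 and 28.5 ± 18.7 CPM (SD, n = 3) in DMSO and after tt-DDE, so that the summed value rests on uneven libraries. The alternative without mitochondrially encoded genes was not run, since those genes were not analysed here. Depth limits genes under about 0.2 CPM, where 3 counts set the floor.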

Other observations

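The tests of the splits of the libraries, of the 50 rows of most counts and of copies on alternate scaffolds, the downstream and with-a-count comparisons of neighbours, and the choice of pathways, were made after the results were seen; the other tests were written down before they were run.

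Several pathways of DNA repair and nucleotide synthesis, which no fixed list covered as a group, fell in the sets of the table's own annotation (camera adjusted p over 311 pathways of 10 to 300 genes tested). The sets for DNA replication (33 of 35 genes lower, camera adjusted p = 9.86e-08) and cell cycle (82 of 115, camera adjusted p = 4.09e-05) fell too. Genes shared with these sets or with the fixed cell cycle lists were not removed, so the falls below may not be separate from theirs. Homologous recombination had 34 of 39 genes lower (median log2 fold change -1.27, adjusted p = 2.10e-05), mismatch repair 21 of 22 (-1.68, adjusted p = 4.81e-05), the Fanconi anemia pathway 37 of 48 (-1.24, adjusted p = 3.86e-04), base excision repair 27 of 33 (-0.99, adjusted p = 5.29e-04) and pyrimidine metabolism 37 of 48 (-1.10, adjusted p = 0.00106), and for each of these adjusted p = 0.492 with an estimated correlation. Non-homologous end-joining was not called, with 7 of 12 genes lower and 3 higher (camera adjusted p = 0.363). In all, 18 pathways were called lower and 6 higher, and none with an estimated correlation. DNA replication too had adjusted p = 0.492 by that version of camera. With degrees of freedom from 6 libraries and adjustment over 311 sets, that version could hardly call any set. Its lack of calls therefore decides little about these falls. Collecting duct acid secretion, a set that holds subunits of the vacuolar proton pump such as ATP6V0D2, had 15 of 21 genes higher (median 0.71, camera adjusted p = 0.0221, and adjusted p = 0.492 with an estimated correlation).

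More rows were detected after tt-DDE: 15575 to 15644 rows had a count, against 14738 to 14854 in DMSO. The rule was a mean under 0.3 CPM in 1 group and of at least 1 CPM in the other, with at least 0.5 CPM in each library of the latter. With further copies of a symbol set aside, 169 genes were gained and 28 lost. After thinning all libraries to the smallest, gained over lost was at least 5.55 in 5 draws, which argues against depth. Olfactory receptor genes, silent in most cells, were at 0.0205 CPM on average after tt-DDE against 0.0305 in DMSO, which argues against genomic DNA or another even background. An expressed neighbour (at least 10 CPM) that overlapped the gene or ended within 10000 bases upstream on its strand was more frequent among gained genes than among other low genes (odds ratio 3.05, 95% interval 2.10 to 4.37), so reads from a neighbour upstream may account for part of the pattern. Taken apart, the odds ratio was 4.30 for upstream neighbours and 1.24 (0.621 to 2.25) for overlapping ones, which showed no enrichment, against 1.95 for downstream ones. Among low genes with a count it was 1.74 for the combined test, 2.37 upstream, 0.792 for overlaps and 1.28 (0.688 to 2.23) downstream. As 124 of the 169 genes had no such neighbour, induction of the genes themselves stays open as an untested biological explanation.

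The fall of cell cycle lists and the rise of chaperone lists were weighed against bias in the counts. After a smooth trend on transcript GC content and length was removed (12144 of 12668 genes), the G2/M median was -3.79 (before: -3.91), and the heat shock and endoplasmic reticulum medians were 2.48 and 2.70, which argues against that bias as the whole cause. The 10 rows of most counts held 10.60% to 10.96% of counts after tt-DDE and 5.13% to 5.27% in DMSO, and leaving out the 50 rows of most counts moved neither the G2/M median (-3.90) nor genes at large (median shift 0.0047), so that test decides nothing. A few abundant genes would lower all other genes alike, but with library size alone the shift over all genes was -0.087 against a G2/M median of -3.99, which argues against them. A response of the cells to tt-DDE is the biological explanation that the design names. The lists were fixed beforehand, but this explanation stays a hypothesis, since treatment cannot be told apart from anything unrecorded that the libraries of a group share.

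Ribosomal protein genes with a further row on an alternate scaffold (RPL7A, RPS9, RPS18 and RPS25, chosen after their values were seen) had a median of 8.57 CPM in DMSO over their summed rows, against 627 CPM for the 56 others. These CPM values are scaled to the column total, without the TMM factors. Over all fixed lists the medians were 0.917 CPM for 54 genes with several rows and 59.3 CPM for 856 with a single row, whereas for glycolysis, with 2 such genes, they were 217 and 74.4 CPM. The low values prompted the comparison, so it is no independent test of a cause. Whether reads that fit several copies were not counted stays open, and no biological explanation was tested.

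The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. In the real split 5244 genes were higher, 5259 lower, 2039 at least 2-fold higher and 2132 at least 2-fold lower, and for each count 1 of the 10 splits, the real one, gave a count as large. The highest of the other splits was 0 genes by edgeR, where 12 to 22 genes had an unadjusted p under 0.05. For the set tests, 7 lists were higher and 5 lower in the real split, with a highest other of 8 for both: 6 of the 10 splits gave as many lists as the 7, and 10 gave as many as the 5. Each of the other splits sets 2 libraries of a treatment against 1, so part of the difference between treatments stays in it, and it is no reference without change for these list counts. The difference between treatments also lies within the groups of such a split and widens the spread that edgeR tests against. Few gene calls were therefore bound to follow, and the 0 genes are no reference for the gene counts either.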
